A study of Mus musculus with 16 samples.

How the data were processed

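RNA sequencing was carried out on 16 mouse hearts, and each library was one heart sample per the labels. The groups were read from the sample titles: 5 wild type hearts, 5 CPT2H-KO hearts, 3 CPT2 single KO hearts and 3 CPT2/USP30 double KO hearts. Per the labels' protocols, RNA was purified on PureLink columns with DNase treatment, and stranded total RNA libraries were made after removal of ribosomal RNA. Per the submitters' processing notes, reads were converted with bcl2fastq and aligned with HISAT2, the genome build was mm10, and DESeq2 1.42.0 was used. The counting program, its annotation and its strand setting are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain.

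The authors deposited 2 tables of raw read counts per gene, whole numbers that had not been normalised. The first holds the wild type and CPT2H-KO libraries and the second the single and double KO libraries. The tables were made with different gene sets, so each comparison was tested within its own table and CPM values were not compared across tables. The first deposited count table lists 14138 genes, none with a total under 151 counts, and its row order follows the strength of the difference between its groups (Spearman 0.98 between row order and rank of p, across genes). Genes with lower counts were therefore not analysed here. The second lists 17831 genes, of which 521 had 0 counts in every library, and 1 further row without a gene name was left out. Spreadsheet software had turned 20 gene symbols of the first table and 25 of the second into dates; the latter were restored through their gene identifiers and the former were left as they stood. The first table repeated 5 symbols. Mitochondrially encoded genes were analysed here in the first table only.

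Totals ranged from 54674422 to 132762776 counts per library in the first table and from 11067969 to 13532716 in the second. Gene counts were tested with edgeR 4.0.16 in R 4.3.3: genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and a quasi-likelihood F test compared the groups. Adjusted p-values are from the Benjamini-Hochberg procedure with a threshold of 0.05, and standard errors (SE) are the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes and are given as mean ± SD. The labels do not say whether hearts shared litters, and p-values measure the spread between these samples.

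Before the data were examined, 45 gene lists were fixed for pathways, complexes and cell type markers, of which those with at least 4 tested members were used. Lists were compared with other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The fry test asked whether the members of a list moved one way on balance. The rule for named genes was also fixed then. It takes Cpt2 and Usp30 and the 10 genes with the largest change each way among those past the threshold, with an average log2 CPM of at least 1 and no overlap between groups, leaving out predicted and sex-linked genes. To these it adds up to 4 members with the smallest p of each list described, and Nppa, Nppb, Myh6, Myh7, Fgf21, Gdf15, Pdk4, Pink1, Bnip3 and Sqstm1; some genes that the rule names are not reported here. A further planned test took the genes called in CPT2H-KO hearts as sets in the double against single KO comparison, which shares no library with the first.

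The edgeR gene test and camera with the preset correlation were tested on simulated counts. These were drawn from the means, dispersions and library sizes of the real libraries, with 200 changed genes for the gene test. Camera with an estimated correlation, fry, DESeq2, limma-voom and the test of CPT2H-KO genes as sets were not run on simulated counts. For CPT2H-KO against wild type, with 14116 genes, 29.9% of genes changed by a log2 fold of 0.5 were recovered, 68.7% of those changed by 1 and 98.5% of those changed by 2, and 6 unchanged genes were called. For double against single KO, with 12913 genes, the shares were 3.03%, 44.6% and 93.8%, and 11 unchanged genes were called. A list of complex I genes moved by 0.3 was called in both simulations, beside 0 unchanged lists in the first and 2 in the second. Simulated genes were drawn independently of each other, while the estimated correlation within the real complex I list was 0.688 in the first comparison. The simulated counts of lists therefore do not measure how often real unchanged lists are called. Libraries of a group were checked for duplication by a chi-square comparison of their counts, and every pair differed by at least 10.7 times the sampling noise. Alternatives covered the scaling, the filter, DESeq2 1.42.0, limma-voom, a replicate block, a sex term, an atrial covariate and the removal of each library in turn. Gene positions are from GENCODE M21, on GRCm38, which is the mm10 assembly.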

Results

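The series profiled total RNA of mouse hearts in which carnitine palmitoyltransferase 2 (CPT2), the inner mitochondrial membrane enzyme that releases long-chain acyl groups for beta-oxidation, was deleted in cardiomyocytes. A second part of the series added deletion of USP30, a deubiquitinase of the outer mitochondrial membrane that opposes mitophagy, the removal of damaged mitochondria. A pair of comparisons follows from the labels: 5 CPT2H-KO hearts against 5 wild type hearts, and 3 CPT2/USP30 double KO hearts against 3 CPT2 single KO hearts. Totals were 55905339 to 132762776 counts per wild type library and 54674422 to 131049342 per CPT2H-KO library. They were 11067969 to 13532716 per single KO library and 11779115 to 12734379 per double KO library. The mitochondrial 16S rRNA gene mt-Rnr2 took 48.5% ± 1.5 (SD, n = 5) of wild type counts and 53.7% ± 2.9 (SD, n = 5) of CPT2H-KO counts.

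The transcript targeted in each comparison was lower in every library labelled as its knockout than in any library of the reference group. Cpt2 (chromosome 4, 107903981 to 107923610, minus strand, GRCm38) stood at 77.9 ± 15.2 CPM in wild type and 40.4 ± 5.72 CPM in CPT2H-KO hearts (n = 5 each), with no overlap. Its log2 fold change was -0.95 (SE 0.15, edgeR adjusted p = 9.71e-04). The highest CPT2H-KO library was at 44.9 CPM and the lowest wild type library at 53.0 CPM. Usp30 (chromosome 5, 114065461 to 114124720, plus strand, GRCm38) stood at 21.03 ± 2.23 CPM in single KO and 9.39 ± 1.68 CPM in double KO hearts (n = 3 each), again with no overlap. The log2 fold change of Usp30 was -1.16 (SE 0.18), but its edgeR adjusted p over all tested genes was 0.147. Which exons were deleted is not given in the sources used here, and counts over the whole gene include reads from other exons and other cell types.

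**Figure D1:**
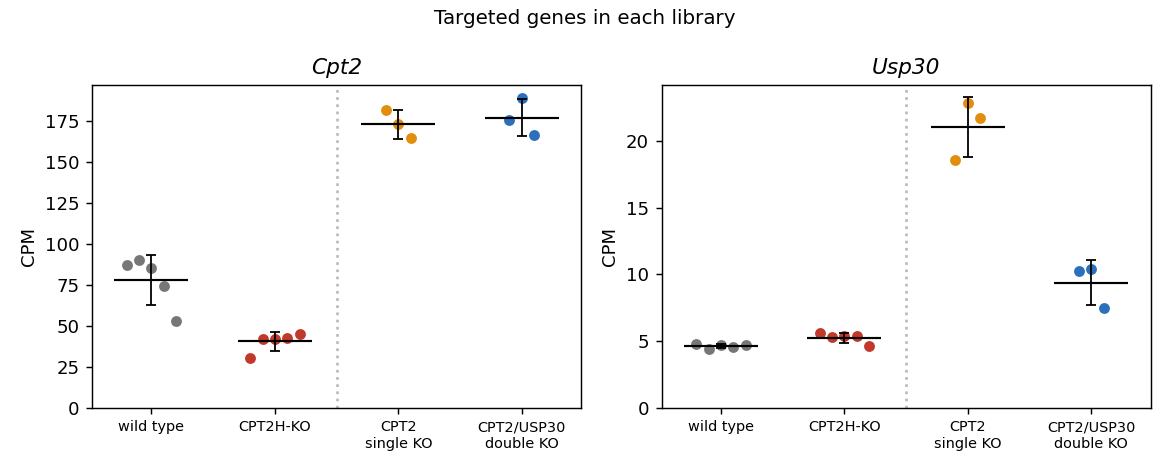
CPM of Cpt2 and Usp30 in each library (points) of the 4 groups, with the group mean (line) and SD (bar); the dotted line separates the 2 count tables, whose CPM are not on a common scale. Cpt2 is lower in all 5 CPT2H-KO libraries than in any wild type library, and Usp30 is lower in all 3 double KO libraries than in any single KO library.

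The first comparison asks how loss of CPT2 in heart muscle changes the cardiac transcriptome. Among the fixed lists, those of integrated stress response, PPAR-alpha target and lipid-handling and extracellular matrix genes were higher in CPT2H-KO hearts, and those of nuclear respiratory chain, ion channel and adult contractile genes were lower. Each was called by camera with a preset correlation, and none with an estimated correlation, where the lowest adjusted p was 0.478. The stress-induced cytokine gene Gdf15 rose from 0.562 ± 0.430 to 20.99 ± 7.67 CPM, a log2 fold change of 5.31 (SE 0.44, n = 5 each, edgeR adjusted p = 1.76e-05). Pdk4, whose kinase restrains glucose oxidation, rose from 197 ± 41.4 to 1372 ± 272 CPM. Nuclear genes of complex I fell in 33 of 35 cases while transcripts encoded in mitochondrial DNA rose in 10 of 13 cases. In all, edgeR called 4758 of 14123 tested genes at an adjusted p under 0.05, 2360 higher and 2398 lower. Of these, 962 changed by at least 1 on the log2 scale (514 higher, 448 lower). The groups did not overlap for 24.7% of genes, where chance gives 0.794%. With library totals as the only scaling, 827 genes were called higher and 4832 lower, since that scaling moves the median of all genes by -0.263.

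The 10 genes with the largest rises were Gdf15, Aqp8, Krt18, Cdh4, Nmrk2, Grip1, Lrp8, Cpxm2, Dusp4 and Mthfd2, with log2 fold changes from 5.31 down to 3.59. Aqp8, a water channel gene, went from 0.804 ± 0.167 to 20.1 ± 6.79 CPM. Nmrk2, a nicotinamide riboside kinase gene of striated muscle, went from 1.70 ± 0.511 to 31.4 ± 27.1 CPM. Libraries of CPT2H-KO hearts varied widely for Krt18, Lrp8 and Dusp4, whose SDs exceeded their means. The 10 largest falls were those of Aqp4, Gpr22, Pla2g5, B3galt2, Hcn4, Phkg1, Casq1, Ramp1, Ces1d and Lrrc3b, with log2 fold changes from -5.24 to -3.06. The call of Ces1d was lost with the atrial covariate described below (adjusted p = 0.0508), where its log2 fold change was still -2.9. Gpr22, an orphan receptor gene, fell from 27.3 ± 7.12 to 1.10 ± 0.184 CPM (adjusted p = 9.85e-07). Aqp4, a second water channel gene, fell from 9.03 ± 2.92 to 0.208 ± 0.239 CPM.

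Fuel metabolism changed unevenly. Of 20 PPAR-alpha target and lipid-handling genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone). Pdk4 had a log2 fold change of 2.80, Acot2, an acyl-CoA thioesterase gene, one of 1.44, and Acot1, another thioesterase gene, one of 1.27. The camera adjusted p of this list was 7.4e-06 (adjusted p = 0.478 with an estimated correlation). Mitochondrial fatty acid oxidation genes went both ways, with 5 of 22 higher, 4 lower and 13 not called, and the list was not called (camera adjusted p = 0.662; 5 and 4 adjusted over the list alone). Cpt1b (0.56) and Acadl (0.76) rose, while Echs1 (-0.62) and the targeted Cpt2 fell. With library totals as the only scaling the value of Cpt1b was 0.30 and its call was lost (adjusted p = 0.0647). Branched-chain amino acid breakdown genes fell in 9 of 17 cases and rose in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 3.09e-04, and adjusted p = 0.722 with an estimated correlation). Ppm1k, the phosphatase gene that activates branched-chain ketoacid dehydrogenase, fell by 2.10 on the log2 scale, from 74.2 ± 14.4 to 17.3 ± 4.54 CPM.

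Respiratory chain transcripts separated by their genome of origin. Complex I genes of the nucleus had a median log2 fold change of -0.345, with 33 of 35 lower (35 adjusted over the list alone) and camera adjusted p = 2.35e-09. Those of complexes III to V had a median of -0.377, with 31 of 35 lower (32 adjusted over the list alone) and camera adjusted p = 8.13e-11. With an estimated correlation these became adjusted p = 0.722 and adjusted p = 0.671. Examples are Ndufv1 (-0.55), Ndufs1 (-0.51), Cox7a1 (-1.04) and Atp5g2 (-0.70). The 13 mitochondrially encoded protein genes had a median of 0.511, with 10 higher, again 10 adjusted over the list alone, and camera adjusted p = 7.73e-05 (adjusted p = 0.595 with an estimated correlation). Among them mt-Nd5 rose by a log2 fold change of 0.97 and mt-Nd4 by 0.82. The rise was not seen in every library when all mitochondrially encoded genes, rRNA included, are taken as a share of counts. CPT2H-KO replicate 2 had 61.9%, within the wild type range of 57.9 to 63.0%, where the other CPT2H-KO libraries had 67.7 to 68.8%. With library totals as the only scaling, which moves the median of all genes by -0.263, the medians of these lists were -0.605, -0.639 and 0.258. Mt-Nd4l overlaps mt-Nd4 in the genome, so its value of 0.93 is uncertain.

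Genes of the mitophagy pathway that USP30 opposes did not move together. Of 25, 6 rose, 3 fell and 16 were not called (6 and 3 adjusted over the list alone; camera adjusted p = 0.566). Pink1, whose kinase marks damaged mitochondria, fell from 199 ± 22.5 to 96.0 ± 14.1 CPM, a log2 fold change of -1.06 (SE 0.11, adjusted p = 9.67e-05). Optn, an autophagy receptor gene, rose by 1.28, Sqstm1 by 0.34 and Phb2 by 0.38, and Fundc1 fell by 0.48. The calls of Sqstm1 and Phb2 were lost with library totals as the only scaling (adjusted p = 0.572 and 0.37), and that of Sqstm1 also without wild type replicate 3 (adjusted p = 0.055) or CPT2H-KO replicate 2 (adjusted p = 0.0537). Usp30 (0.18, adjusted p = 0.081) and Bnip3 (-0.56, adjusted p = 0.122) were not called by edgeR. Without CPT2H-KO replicate 1 the value of Bnip3 was -0.92 (adjusted p = 0.00118), and without CPT2H-KO replicate 5 that of Usp30 was 0.22 (adjusted p = 0.0307).

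Integrated stress response genes, which ATF4 induces when protein synthesis or mitochondria are disturbed, had a median log2 fold change of 1.15. Of 25, 15 rose and 2 fell, namely Psph and Cth (17 and 2 adjusted over the list alone). The risers include Gdf15, Mthfd2 (3.59), a mitochondrial folate enzyme gene, Asns (3.19), for asparagine synthesis, and Aldh18a1 (1.59), for proline synthesis. The camera adjusted p was 2.33e-09 (adjusted p = 0.478 with an estimated correlation). Fgf21 is not analysed here for this comparison. The cell cycle list rose in 6 of 20 cases and fell in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 3.09e-04, and adjusted p = 0.722 with an estimated correlation). The examples by smallest p were replication licensing genes, Mcm2 (1.85), Mcm5 (1.54), Mcm3 (1.03) and Mcm6 (0.72). With the atrial covariate the calls of Mcm6 (0.52, adjusted p = 0.0531) and of the list (median 0.241, camera adjusted p = 0.0581) were lost.

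Cardiac structural genes shifted. Of 17 fetal and hypertrophy genes, 9 rose and 1, Acta2, fell by 1.75 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00257, and adjusted p = 0.722 with an estimated correlation). The skeletal actin gene Acta1 rose from 163 ± 61.0 to 1257 ± 261 CPM, Ankrd1 from 396 ± 119 to 1112 ± 312 CPM, and the natriuretic peptide gene Nppb from 56.1 ± 35.4 to 230 ± 84.2 CPM (adjusted p = 0.00315). Nppa rose by a log2 fold change of 2.12 with overlapping groups (adjusted p = 0.0229), and its call was lost without wild type replicate 2 (adjusted p = 0.0555), 3 (0.0566) or 4 (0.054) or CPT2H-KO replicate 1 (0.0533). Myh7 (1.27, adjusted p = 0.0968) and Myh6 (0.18, adjusted p = 0.202) were not called, and without CPT2H-KO replicate 1 the value of Myh7 was 0.24. Of 21 adult contractile and calcium-handling genes, 11 fell and 1, Mybpc3, rose (12 and 1 adjusted over the list alone), with Tcap at -2.40, Pln at -1.09 and Tnni3 at -1.03. Their camera adjusted p was 7.24e-05 (adjusted p = 0.478 with an estimated correlation).

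Of 19 ion channel and gap junction genes, 11 fell and 1, Hcn2, rose (11 and 1 adjusted over the list alone; camera adjusted p = 1.39e-05, and adjusted p = 0.478 with an estimated correlation). The pacemaker channel gene Hcn4 fell by 3.85, the inward rectifier gene Kcnj2 by 1.98, the T-type calcium channel gene Cacna1g by 1.15 and Kcnh2 by 1.08. Extracellular matrix genes rose in 25 of 30 cases and fell in 0 (28 and 0 adjusted over the list alone), with a median of 1.32 and camera adjusted p = 1.16e-09 (adjusted p = 0.671 with an estimated correlation). Cilp rose from 13.2 ± 2.55 to 81.5 ± 46.5 CPM, Col8a1 from 19.97 ± 3.25 to 102 ± 60.9 CPM and Col1a1 from 71.2 ± 21.1 to 189 ± 62.0 CPM. Genes of the cholesterol synthesis list rose in 9 of 17 cases and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.478 with an estimated correlation), with Insig1 at 1.32. The immediate early list rose in 8 of 17 cases and fell in 1 (8 and 1 adjusted over the list alone), with Egr1 at 2.20 and Jun at 0.82. Its camera adjusted p was 0.0077 (adjusted p = 0.866 with an estimated correlation and fry adjusted p = 0.105). The median of the immediate early list ranged from 0.595 to 1.49 over 16 alternatives, and its call was kept in 13.

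Of 42 lists tested here, 14 were called by camera with the preset correlation (8 higher, 6 lower), 0 with an estimated correlation and 17 by fry, 12 of them shared with camera. Atrial and Y-linked transcripts differed between libraries. The atrial light chain gene Myl7 was at 25.4 to 194 CPM in all 5 wild type libraries, at 0.285 to 0.610 CPM in CPT2H-KO replicates 2, 3 and 4, at 14.1 CPM in replicate 1 and at 144 CPM in replicate 5. Y-linked transcripts were at background in 1 wild type and 2 CPT2H-KO libraries. With the mean of Myl7, Myl4 and Sln as a covariate, chosen after the data were seen, 2856 genes were called, 2589 of them among the 4758. Cpt2 then had a log2 fold change of -0.89 (adjusted p = 0.018).

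**Figure D2:**
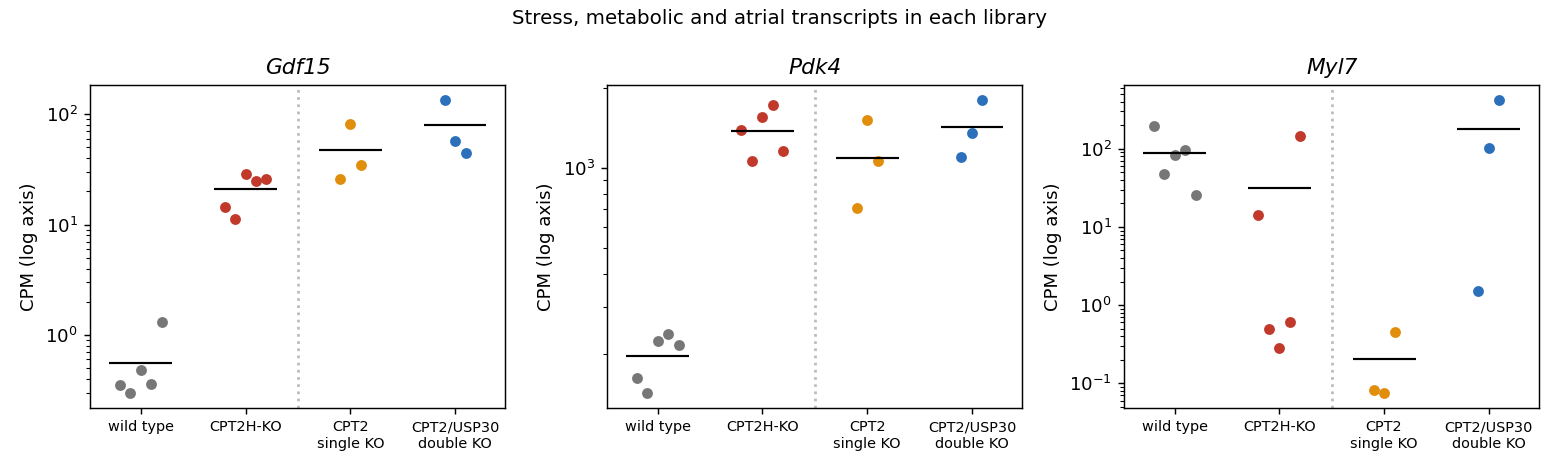
CPM on a log axis of Gdf15, Pdk4 and Myl7 in each library (points) with group means (lines); the dotted line separates the 2 count tables, whose CPM are not on a common scale. Gdf15 and Pdk4 are higher in all 5 CPT2H-KO libraries than in any wild type library, while Myl7 varies within groups and reaches 425 CPM in double KO replicate 3.

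The second comparison asks what loss of USP30 changes in hearts that already lack CPT2. Here edgeR called 0 of 12997 genes (lowest adjusted p = 0.127). At an unadjusted p under 0.05 there were 942 genes, 592 higher and 350 lower, where chance gives 650. DESeq2 called 113 genes, and limma-voom called 0. The groups did not overlap for 11.8% of genes, where chance gives 10%. Without double KO replicate 1, which leaves the double KO libraries that carry atrial transcripts, edgeR called 114 genes, 104 of them higher. Among them were Usp30 (-1.24, adjusted p = 0.0218) and the atrial genes Myl7 (10.35) and Myl4 (7.55). Without single KO replicate 3 it called 4. Cpt2 was at 173 ± 8.72 CPM in single KO and 177 ± 11.4 CPM in double KO hearts (log2 fold change 0.03, SE 0.14, n = 3 each, edgeR adjusted p = 0.983).

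Stress and metabolic genes that rose in CPT2H-KO hearts did not pass the test in double against single KO hearts. Gdf15 was at 47.2 ± 29.9 and 79.2 ± 49.2 CPM (0.74, SE 0.48, edgeR adjusted p = 0.811), and Pdk4 at 1092 ± 405 and 1417 ± 357 CPM (0.37, SE 0.28, edgeR adjusted p = 0.852). Over the alternatives Gdf15 ranged from 0.11 to 1.74 and Myh7 from 0.87 to 3.07. Nppa (0.74), Nppb (-0.48), Myh7 (1.55) and Myh6 (0.23) were not called, nor were Pink1 (0.19), Bnip3 (-0.07) and Sqstm1 (0.28). Of 26 mitophagy genes, 0 were called, and 1, Usp30 itself, passed when adjusted over the list alone (camera adjusted p = 0.0667). Fgf21 had 1 to 5 counts per library and was removed by the low-count filter.

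Several lists were called by camera with the preset correlation, 18 of 40 (13 higher, 5 lower), but 0 with an estimated correlation and 0 by fry, whose lowest adjusted p was 0.0636. Cell cycle genes were lower, with a median of -1.08 (camera adjusted p = 5.21e-15, and adjusted p = 0.345 with an estimated correlation), and 9 of 20 passed as lower when adjusted over the list alone. That median was -0.191 with a sex term and -0.2 without both single KO libraries with Y-linked transcripts, alternatives chosen after the data were seen. Both set the double KO libraries against single KO replicate 3 alone, so they are not separate evidence. The cell cycle list kept its call in 10 of 14 alternatives. Mki67, the proliferation marker, was at 32.3 ± 17.7 CPM in single KO and 8.71 ± 6.06 CPM in double KO hearts, and Top2a at 14.1 ± 8.43 and 4.01 ± 2.60 CPM. The log2 fold change of Mki67 ranged from -2.59 to -0.49 over the alternatives. Red blood cell markers were lower (median -0.563, camera adjusted p = 1.04e-07, and adjusted p = 0.337 with an estimated correlation), with Slc4a1 at -1.77 and Hbb-bs at -0.64. Endothelial markers were lower (median -0.265, camera adjusted p = 0.00161, and adjusted p = 0.471 with an estimated correlation), led by Cdh5 at -0.56. That median was -0.0175 with the atrial covariate and -0.0273 without both double KO libraries with atrial transcripts. The hypoxia list (median -0.08, with Egln3 at -0.78 and Ankrd37 at -1.68) and the heat shock list (median -0.369, with Hspa8 at -0.38) were also lower. Their camera adjusted p were 0.0306 and 0.00111, and adjusted p = 0.337 and 0.438 with an estimated correlation. Of 11 hypoxia genes, 3 were above 0, among them Ndrg1 (0.08 to 0.47 over the alternatives). Adjusted over the list alone, 3 red blood cell and 2 hypoxia genes passed as lower, and 0 endothelial and 0 heat shock genes did. Over 14 alternatives the call was kept in 12 for red blood cell, 7 for endothelial, 7 for heat shock and 5 for hypoxia genes.

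Some further lists, among them fibroblast and macrophage markers, were called higher in double KO hearts by camera with the preset correlation. Smooth muscle and pericyte markers were not called (median 0.016, camera adjusted p = 0.276). Fibroblast markers had a median of 0.521 (camera adjusted p = 7.81e-09, and adjusted p = 0.287 with an estimated correlation), and 4 of 10 passed as higher when adjusted over the list alone. Gsn, for the actin-severing protein gelsolin, was at 1312 ± 65.3 CPM in single KO and 2694 ± 95.0 CPM in double KO hearts, a log2 fold change of 1.04 (SE 0.15, edgeR adjusted p = 0.127). Dcn stood at 0.82, Dpt at 0.96 and Dpep1 at 0.59. Macrophage markers had a median of 0.437 and inflammatory cytokine genes one of 0.674, with camera adjusted p = 8.45e-05 and 2.16e-04, and adjusted p = 0.471 and 0.292 with an estimated correlation. Adjusted over the list alone, 0 genes of either passed. Over 14 alternatives the macrophage median ranged from 0.22 to 0.934, and its call was kept in 11. The cytokine median ranged from 0.455 to 1.06, and its call was kept in 12. Circadian clock genes were higher (camera adjusted p = 0.00111, and adjusted p = 0.287 with an estimated correlation), with 3 of 15 passing adjusted over the list alone. The clock list, with a median of 0.12, lost its call with the atrial covariate (camera adjusted p = 0.294), but its median was then 0.129. Without both double KO libraries with atrial transcripts the clock median was 0.12, so it did not shrink in either alternative. Ciart was at 1.28 and Dbp, a clock output gene, at 0.66.

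Atrial markers were higher (median 2.90, camera adjusted p = 2.8e-08, and adjusted p = 0.287 with an estimated correlation; 4 of 6 adjusted over the list alone), and so were mesothelial markers (median 1.77, camera adjusted p = 9.22e-06, and adjusted p = 0.287 with an estimated correlation; 6 of 8 adjusted over the list alone). With the atrial covariate these medians were 0.743 and -0.0467, and without both double KO libraries with atrial transcripts the mesothelial median was 0.296. Myl7 and Myl4 are part of both the covariate and the atrial list, so the fall of the atrial median was built in. The mesothelial list still passed camera with the covariate (camera adjusted p = 0.0171), although its median was below 0. Myl7 was at 0.0749 to 0.458 CPM in the single KO libraries, at 1.49 CPM in double KO replicate 1, and at 102 and 425 CPM in replicates 2 and 3. Y-linked transcripts were at background in all 3 double KO libraries and in single KO replicate 3, and were present in single KO replicates 1 and 2. Without both double KO libraries with atrial transcripts, an alternative chosen after the data were seen, edgeR called 36 genes with 1 library left in the double KO group, assumed to vary like the others. With a sex term it called 0.

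Energy metabolism lists were compared between single and double KO hearts. Nuclear complex I and complexes III to V genes had medians of 0.117 and 0.12 (camera adjusted p = 0.0311 and 0.0222, and adjusted p = 0.976 for each with an estimated correlation), with 0 of 35 genes of either passing, also adjusted over the list alone. Over the alternatives these medians ranged from 0.00805 to 0.422 and from 0.0411 to 0.375, highest with the atrial covariate. PPAR-alpha target and lipid-handling genes had a median of 0.227 (camera adjusted p = 0.00196, and adjusted p = 0.633 with an estimated correlation; 1 gene adjusted over the list alone), led by the uncoupling protein gene Ucp3 at 0.74. With the atrial covariate that median was -0.0206, without both double KO libraries with atrial transcripts it was 0.0028, and it ranged from 0.0415 to 0.33 without single libraries. The calls were kept in 7 of 14 alternatives for complex I, 7 for complexes III to V and 9 for PPAR-alpha target and lipid-handling genes. Antioxidant response genes had a median of 0.27 (camera adjusted p = 5.74e-04, and adjusted p = 0.462 with an estimated correlation; 0 adjusted over the list alone), with Mt2 at 1.12 and Gstm1 at 0.80. That call was kept in 9 of 14 alternatives, and the median was 0.118 with the sex term and 0.029 without double KO replicate 2. Over the alternatives Mt2 ranged from 0.51 to 2.01 and Gstm1 from 0.41 to 0.95. The fetal and hypertrophy list was called higher (median 0.075, camera adjusted p = 0.0454, and adjusted p = 0.783 with an estimated correlation; 3 adjusted over the list alone), and its smallest p were those of the atrial genes Myl7 and Myl4. Its median was -0.0652 without single KO replicate 1 and -0.148 without double KO replicate 1, and the call was kept in 7 of 14 alternatives.

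**Figure D3:**
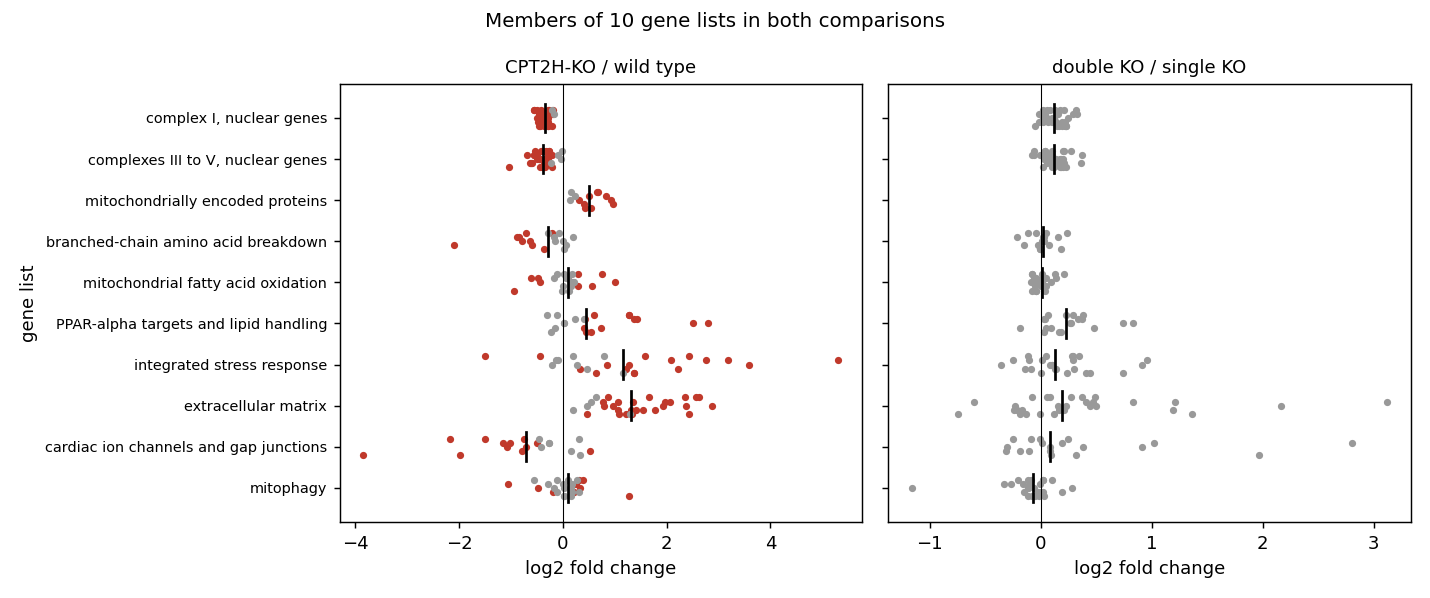
Log2 fold changes of the members of 10 gene lists (rows) in CPT2H-KO against wild type (left) and double against single KO (right); red points passed the edgeR adjusted p threshold, grey points did not, and black bars are list medians. The horizontal axes differ in range, and mitochondrially encoded genes are not analysed on the right. On the left the nuclear complex I median is -0.345 and the mitochondrially encoded median 0.511, and on the right 0 genes passed.

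Whether USP30 loss moves the CPT2-dependent genes back was tested with the genes called in CPT2H-KO hearts as sets. The 2156 genes higher in CPT2H-KO hearts and tested in both had a median log2 fold change of -0.05 in double against single KO hearts, and 40.6% of them were above 0 (camera p = 0.0055, p = 0.304 with an estimated correlation, fry p = 0.368). The 2075 lower genes had a median of 0.0425, with 59.1% above 0 (camera p = 0.0512, p = 0.494 with an estimated correlation, fry p = 0.429). The subset of lower genes called at an edgeR adjusted p under 0.01 with an absolute log2 fold change of at least 1 in CPT2H-KO hearts had a median of 0.254 and was called by camera. That subset, like the higher genes under the same cut, was run only by camera with the preset correlation. It was not tested with an estimated correlation, by fry or with the atrial covariate. The higher genes kept their camera call under that cut, and their median lay between -0.107 and -0.00675 in every alternative. With the atrial covariate the median of the full set of lower genes was -0.0327, and without both double KO libraries with atrial transcripts it was -0.0335. Both alternatives rest largely on double KO replicate 1 against the single KO libraries, so they are not separate evidence. Across 12017 genes tested in both, which are not independent replicates, the fold changes correlated with Spearman rho of -0.139 and Pearson r of -0.171. The atrial score, the mean log2 CPM of Myl7, Myl4 and Sln, was 3.82 to 6.86 in wild type and -0.27 to 6.53 in CPT2H-KO libraries. It was 0.05 to 0.37 in single KO and 1.12 to 8.53 in double KO libraries. Atrial transcripts thus tended to be lower in CPT2H-KO hearts and higher in double KO hearts. Whether this gave the negative correlation was not tested. Without single KO replicate 2 the median of the higher genes was -0.00675, and without double KO replicate 2 that of the lower genes was 0.00476.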

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

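The tests of scaling, atrial tissue and sex were chosen after the results were seen; the length test was set before its result was seen.

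Of 182 sets of 5 libraries, 17 held 1 library whose gap to the nearest other was large for the range, where chance gives about 1 in 20. CPT2H-KO replicate 1 stood apart for Cpt2 (30.4 CPM, the others 42.0 to 44.9), Myh7 (527, the others 63.9 to 123), Krt18 (42.7, the others 2.36 to 8.51), Cdh4 (7.75, the others 17.3 to 19.6), Nmrk2 (79.1, the others 14.5 to 27.0), Dusp4 (26.1, the others 3.08 to 6.67), Pln (757, the others 1030 to 1080) and Col1a1 (294, the others 141 to 183). CPT2H-KO replicate 5 stood apart for Phkg1 (2.44 CPM), Acta2 (62.7), Myl7 (144) and Stard10 (19.7). CPT2H-KO replicate 2 had 48.7% of its counts on mt-Rnr2, where the others of its group had 54.0 to 55.9% and wild type libraries 46.3 to 50.3%. In wild type, replicate 1 stood apart for Nppa (614 CPM, the others 122 to 180) and Myh6 (10300 CPM), replicate 5 for Gdf15 (1.32 CPM, the others 0.297 to 0.478) and replicate 3 for Mcm6 (4.34 CPM, the others 5.66 to 6.20).

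The lower nuclear respiratory chain genes of CPT2H-KO hearts were tested against 3 technical explanations. Across genes, log2 fold changes rose with transcript length (Spearman 0.195). The complex I median nevertheless lay -0.251 from that of genes matched for length and expression, and that of complexes III to V lay -0.297, both below all 1000 matched draws, which argues against length as the whole cause. With mitochondrial and ribosomal RNA genes removed before scaling the medians were -0.332 and -0.365. That removal moved the median of all genes by 0.013, so those genes had little weight in the scaling used. Other faults of scaling were not tested by it. With the atrial covariate the medians were -0.288 and -0.319, so the covariate did not remove most of the fall. The loss of CPT2 stays open as a hypothesis, together with explanations that were not tested, such as a difference in RNA quality.

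Atrial transcripts in double KO replicates 2 and 3 may come from atrial tissue in the piece taken. Of 4 fixed atrial markers that were low in single KO hearts, 3 (Myl7, Myl4 and Sln) were higher in replicate 3 than in replicate 2 by similar ratios of 4.16, 3.46 and 4.84, while Bmp10 had a ratio of 45.6; the list shares Myl7 and Myl4 with the fetal list. Sln and Bmp10, which the low-count filter removes, were added to this test after a first result on Myl7 and Myl4 alone, which was too few markers to decide. Whether Bmp10 reflects a different part of the atria was not tested. A wide spread also arose in hearts not labelled as USP30 knockouts. In CPT2H-KO hearts Myl7 had 14 counts in replicate 3 and 16732 in replicate 5, and Bmp10 had 7 and 15339. In wild type replicate 3 Bmp10 had 9 counts beside 11962 of Myl7. Loss of USP30 as the cause cannot be told apart from tissue sampling with 3 libraries, of which replicate 1 was at 1.475 CPM of Myl7 (scaled over all genes of the table; 1.49 CPM scaled over the tested genes).

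The medians of opposite sign for CPT2-dependent genes in double KO hearts were weighed against atrial tissue and sex. Whether those genes moved at all is not settled, since neither set was called with an estimated correlation or by fry and 4 of 10 splits gave medians as far from 0 for each. With the atrial covariate the medians of genes higher and lower in CPT2H-KO hearts were -0.0895 and -0.0327, from -0.05 and 0.0425. The camera call of the higher genes was then lost, for a reason not tested, and other splits of the 6 libraries reached 0.0904 and 0.0869, so atrial tissue cannot be told apart from loss of USP30 for either set. With a sex term the medians shrank to -0.0234 and 0.013, and sex cannot be told apart from loss of USP30 either, since no double KO library had Y-linked transcripts. That fit in effect sets the double KO libraries against single KO replicate 3 alone. Atrial tissue, sex, an effect of USP30 loss and no movement at all stay open.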

How the results depend on the processing

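The atrial covariate, the removal of both double KO libraries with atrial transcripts, the removal of both single KO libraries with Y-linked transcripts and the sex term in the second comparison were chosen after the data were seen; where a cause is not named below, the cause was not tested. The 4758 genes called in CPT2H-KO hearts became 2482 at an adjusted p under 0.01, 962 with an absolute log2 fold change of at least 1 and 2856 with the atrial covariate, and stayed within 1.5 times in the other 20 alternatives, from 3682 to 4787 without single libraries. Cpt2 kept its call in all 21 alternatives. The 14 lists called there became 0 with an estimated correlation. In double against single KO hearts the count of 0 became 113 with DESeq2, 1 with the replicate block, 25 with the atrial covariate, 36 without both libraries with atrial transcripts, and 0 to 114 without single libraries; Usp30 was called with DESeq2 (-1.18, adjusted p = 2.43e-04) and ranged from -1.26 to -1.03 without single libraries. The 18 lists called there became 0 with an estimated correlation and 0 with fry, and other alternatives changed which lists were called: 12 of the 18 stayed among 26 with the atrial covariate, 12 among 27 without both libraries with atrial transcripts, 9 among 13 with the sex term, 8 among 15 without both libraries with Y-linked transcripts and 11 among 18 without double KO replicate 2. Same-numbered libraries correlated at -0.087 to 0.23 in the first comparison and -0.205 to 0.167 in the second, and not every library correlated best with its own number, so the numbers were not taken to pair samples; with the replicate block 4179 genes were called in the first comparison. Sex was to be fitted where both groups hold both kinds of library, which double KO hearts do not, so the sex term there rests on the single KO libraries. Its fold changes in effect set the double KO libraries against single KO replicate 3 alone. The same holds without both libraries with Y-linked transcripts, so the 2 alternatives are not separate evidence. Removal of mitochondrial genes was not run in the second comparison, as those genes are not analysed in that table. Leaving out 1 single KO or double KO library leaves 2 in its group, and removing both with atrial or both with Y-linked transcripts leaves 1, assumed to vary like the others. The atrial score was 0.05 to 0.37 in single KO libraries and 1.12, 6.49 and 8.53 in double KO replicates 1, 2 and 3. Fits with the atrial covariate there thus rest largely on double KO replicate 1, as do those without both libraries with atrial transcripts.

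The median of genes higher in CPT2H-KO hearts lost its camera call with an estimated correlation (-0.05), fry (-0.05), the sex term (-0.0234), the atrial covariate (-0.0895), without both libraries with atrial transcripts (-0.0864) and without single KO replicate 2 (-0.00675), and ranged from -0.107 to -0.00675 without single libraries. That of the lower genes passed in 9 of 16 fits without single libraries, at an adjusted p under 0.01 and absolute log2 fold change of 1 or more (0.254), with DESeq2 size factors (0.0309) and with the replicate block (0.0337), turned to -0.0327 with the atrial covariate and -0.0335 without both libraries with atrial transcripts, and ranged from 0.00408 to 0.0604 without single libraries. With library totals only, which moves the median of all genes by -0.263, Usp30 (-0.0853) and Myh6 (-0.0962) turned lower in CPT2H-KO hearts. In double against single KO hearts, the atrial covariate turned Nppb to 0.31, Myh6 to -0.22, Pdk4 to -0.11, Pink1 to -0.057, Bnip3 to 0.018, Slc27a1 to -0.0206, Il33 to -0.19, Stard10 to -0.31, Lrrn4 to -0.61 and Krt19 to -0.18, and the medians of the PPAR-alpha (-0.0206) and mesothelial (-0.0467) lists. Without both libraries with atrial transcripts Nppb was at 0.26, Myh6 at -0.25, Pdk4 at -0.00229, Pink1 at -0.12, Bnip3 at 0.00891, and Lrrn4 at -0.0377. The sex term turned Dnajb1 to 0.18, Hspa1a to 0.80 and the heat shock median to 0.0428, and the removal of both single KO libraries with Y-linked transcripts turned them to 0.17, 0.79 and 0.0353. Without single libraries, Cpt2 ranged from -0.0184 to 0.0656, Bnip3 from -0.16 to 0.0255, Nppa from -0.28 to 1.21, Nppb from -1.09 to -0.21, Myh6 from 0.00103 to 0.41, Pdk4 from 0.12 to 0.68, Pink1 from -0.0243 to 0.32, the fetal and hypertrophy list from -0.148 to 0.216 and the cytosolic ribosomal list from -0.0293 to 0.264. At 11067969 to 13532716 counts per library and 3 libraries a group, 3.03% of simulated genes changed by a log2 fold of 0.5 were recovered, so small differences were not detectable.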

Other observations

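Further lists were examined in CPT2H-KO hearts. Of 75 mitochondrial ribosomal protein genes, 30 fell and 7 rose, with a median of -0.164 (camera adjusted p = 0.0128, adjusted p = 0.89 with an estimated correlation and fry adjusted p = 0.0719). With the atrial covariate the call was lost (camera adjusted p = 0.0632), but the median was then -0.167. Of 18 TCA cycle genes 8 fell and 0 rose without camera calling the list (camera adjusted p = 0.0657, fry adjusted p = 0.0436). Of 11 genes of mitochondrial fusion and fission, 6 fell and 0 rose (camera adjusted p = 0.167, fry adjusted p = 0.00892). Glycolysis genes went both ways, with 4 of 22 higher and 5 lower. Of 12 genes of the mitochondrial unfolded protein response, 4 rose and 1 fell (camera adjusted p = 0.165, fry adjusted p = 0.0178), and of 31 autophagy and lysosome genes 7 rose and 6 fell (camera adjusted p = 0.753). Macrophage markers were mostly not called, with 2 of 14 higher and 1 lower, and lists of interferon response and inflammatory cytokine genes were not called (camera adjusted p = 0.285 and 0.831).

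Other splits of the samples were counted as planned. Of 100 splits of the 10 wild type and CPT2H-KO libraries, only the real one gave as many as 4758 called genes. The highest other gave 1, so chance is unlikely to give that count. Other splits mix the genotypes, which widens the spread within groups, so the gap from 4758 to 1 does not measure how unlikely. For the number of called lists, 58 of the 100 splits gave at least the real 14, so that number does not set the real split apart. With 5 libraries a group, every other split holds unequal numbers of each genotype and so keeps part of the genotype difference. The list counts of other splits thus do not measure what chance gives. The highest other split gave 22 lists. The 10 splits of the single and double KO libraries are too few for a share under 0.05. There the real split gave 0 called genes, as did the highest other, so all 10 were level at 0 and the count carries no information. For the lists 5 gave at least 18 and the highest other gave 26. For the medians of genes higher and lower in CPT2H-KO hearts, 4 and 4 splits lay as far from 0 as -0.05 and 0.0425, and the highest others were 0.0904 and 0.0869.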
